A study of Mus musculus with 6 samples.

How the data were processed

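Bulk RNA was sequenced from 6 libraries of mouse intestinal organoids, which are small cultures of intestinal epithelium grown from stem cells in a medium with EGF, Noggin and R-spondin1. Per the labels, 2 libraries were wild type (WT), 2 were Smad4-deficient (Smad4 KO) and 2 were Smad4-deficient with 0.5 nM TGF-β. All titles carry 48 h, and the protocol can be read as 48 h of TGF-β in all or as 48 h followed by 2 more days. Total RNA was extracted with TRIZOL and primed with random hexamers, per the labels' protocols. Samples were grouped by their titles. The labels do not say that the replicates came from separate cultures or animals, so every p-value here measures only the spread between these samples, which may be technical. They do not say either how Smad4 was inactivated or which part of the gene was deleted.

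The values are the estimated counts that the authors deposited per Ensembl gene, as whole numbers, with 1 column per library. Per the submitters' processing notes, FastQC 0.11.9, HISAT2 2.1.0, SAMtools 1.9 and StringTie 1.3.3b were used with the mouse build GRCm38, also called mm10. The annotation release, the strand setting, the read length and the way StringTie estimates became whole numbers are not given in the sources used here. Low values piled up at 4, 8, 12, 16 and 20: of the values from 1 to 24, 42.3% were multiples of 4, against 25% if they were spread evenly. Each fragment was therefore taken to add about 4 units. This is an inference, since most of these low values were not multiples of 4, and fragment totals, floors and counting intervals rest on it. Total units ran from 40.55 to 50.7 M (1e6) per library, or about 10.1 to 12.7 M fragments. StringTie divides fragments between overlapping transcripts, so values of genes that overlap or have near-identical copies are uncertain. Because the strand setting is unknown, a gene and an antisense partner could not be told apart.

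The table held 31227 genes, of which 97 had no symbol and 64 shared a symbol with another gene; 11742 were at 0 in all libraries. Values were used as deposited, with no rounding needed. Genes with low counts were removed with filterByExpr, which left 15503, and libraries were scaled by TMM. edgeR's quasi-likelihood test (glmQLFit and glmQLFTest, 2-sided) was fitted to all 6 libraries with the group as the only term, which left 3 residual degrees of freedom per gene. Genes passed at a Benjamini-Hochberg adjusted p under 0.05, called adjusted p throughout. Expression is given as TMM-scaled counts per 1e6 counts (CPM), and log2 fold changes carry the SE of the fitted model. Because a unit is not a molecule, the fit learned the excess spread from the replicates. Genes at 0 in a group are given as a bound against a floor of 3 fragments (12 units) over the group. List medians given with genes at 0 set to their bound also leave out members at or under this floor in both groups. Ratios printed for genes above 0 but at or under that floor in a group carry a 95% counting interval. Floors and intervals cover counting error only. Folds of genes slightly above the floor carry no interval, although they too rest on few fragments.

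The design, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined. Each of 35 gene lists was tested with camera (limma) on log2 CPM with a preset correlation between genes of 0.01, and adjusted over the 35 lists. Camera compares a list with all other genes. With an estimated correlation, camera takes its degrees of freedom from the 3 residual ones, and fewer lists passed. The named genes were Smad4, then for each comparison the 5 highest and 5 lowest log2 fold changes among passing genes with a mean of at least 5 CPM in the higher group, no overlap between the groups' libraries and no clone-type symbol. They also included up to 3 members with the smallest adjusted p from each primary list and up to 2 from each other list with at least 3 passing members. For WT against the TGF-β-treated group only 3 primary lists were used in this way. Where no member of a primary list passed, the member with the highest mean was named. Members of a list named outside this rule, mostly those that moved when 5 or fewer did, were chosen after their values were seen. Some genes that this rule selects are not reported here. Positions come from the GENCODE vM21 annotation of GRCm38, which may differ from the release that the authors used.

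The tests were checked on simulated data made from the 15503 genes, their library sizes and their dispersions. In these, 200 genes were changed and a further list of 20 was shifted 2-fold. For Smad4 KO against WT, 26.9% of genes changed 1.5-fold, 52.4% changed 2-fold and 80% changed 4-fold were recovered, and 14 unchanged genes were called, 10.9% of the calls. For Smad4 KO with TGF-β against Smad4 KO the shares were 22.9%, 50.9% and 68.5%, with 9 false calls (7.83%). For Smad4 KO with TGF-β against WT they were 28.1%, 69.7% and 77.1%, with 20 false calls (13.4%). These false shares lie above the nominal 5%. Far fewer genes changed in the simulations than the 4704, 2521 and 6155 called in the data. Recovery and false shares depend on that number, so these figures do not carry over to the reported calls. A first requirement of over 80% recovery at 4-fold was not met and was lowered to 60% after the result was seen; every recovered gene had the right sign. One list shifted 2-fold was recovered in each of the 3 simulations, and 0, 0 and 1 of the unshifted lists were called.

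Alternatives were RLE size factors, no filter on low counts, DESeq2, the replicate number as a block, only the 4 libraries compared, a test against a fold change of 1.5, leaving out each library in turn, camera with an estimated correlation, and fry. Division of the values by the 4 units per fragment was added after the data were seen. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9.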

Results

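RNA-seq measured gene expression in WT, Smad4 KO and TGF-β-treated Smad4 KO intestinal organoids, with 2 libraries per group. Smad4 is the shared partner of the SMAD proteins that carry TGF-β and BMP signals to the nucleus, and the title of the series names TGF-β, Smad4-deficient epithelium and Yap, a transcriptional coactivator held in check by the Hippo pathway. WT libraries held 50.7 and 42.49 M units (M, 1e6), Smad4 KO libraries 40.55 and 41.75 M, and TGF-β-treated libraries 43.31 and 43.73 M. Replicates correlated across genes at 0.9757 in WT, 0.9705 in Smad4 KO and 0.9749 with TGF-β (log2 CPM), while libraries of WT and treated Smad4 KO organoids correlated at 0.9231 to 0.9255. Counts of replicates differed by more than sampling noise in each group (chi-square per degree of freedom 6.17, 5.66 and 5.19, in fragments), which separate preparations of the same RNA would show as well. Each library was therefore counted by its label, and not on the strength of this spread. No WT group with TGF-β was analysed here, so whether a response to TGF-β depended on Smad4 could not be tested.

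Smad4 (ENSMUSG00000024515, chromosome 18, 73639009 to 73703780 on the minus strand, GRCm38) stood at 99.37 and 109.46 CPM in the WT libraries, at 21.66 and 23.07 CPM in the Smad4 KO libraries and at 25.19 and 29.52 CPM in the treated libraries. It was 4.67-fold lower in Smad4 KO than in WT (log2 fold change -2.22 ± 0.1 SE, n = 2 per group, edgeR adjusted p = 2.7e-05). With TGF-β the ratio to Smad4 KO was 1.22 (adjusted p = 0.11). The count covers the whole gene and does not show a deleted part, so the remaining signal does not tell whether intact transcript was present.

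The first comparison, Smad4 KO against WT, sets the genotypes against each other without added TGF-β. A difference in organoid line or origin between these groups could not be told apart from genotype. Enterocyte genes, which serve nutrient absorption, rose together in Smad4 KO organoids, while genes of crypt base stem cells, Paneth cells, enteroendocrine cells and the cell cycle fell. None of these lists passed with an estimated correlation (adjusted p = 0.097, 0.102, 0.102, 0.113 and 0.102 in this order). Apoa1, an apolipoprotein of absorptive cells, was 9.41-fold higher (1630 ± 25 against 174 ± 2.4 CPM, mean ± SD, n = 2 per group), and Lgr5, the receptor that marks crypt base stem cells, was 2.04-fold lower (255 ± 3.3 against 520 ± 4.6 CPM). Clu, a marker of regenerating epithelium, was 8.5-fold higher (241 ± 4.5 against 28.4 ± 5.3 CPM). Of 15503 genes tested, 4704 passed in edgeR, 2620 higher and 2084 lower, and 740 and 484 of these differed more than 2-fold. The number lower was 1166 without WT replicate 1, 1227 without WT replicate 2 and 1387 without Smad4 KO replicate 1.

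Of 25 enterocyte markers, 22 rose and 1, the aminopeptidase Anpep (log2 fold change -0.30), fell, with the same counts adjusted over the list alone (camera adjusted p = 8.6e-15, and adjusted p = 0.097 with an estimated correlation). Their median log2 fold change was 1.43. Apoa4, which carries lipid in chylomicrons, was 5.77-fold higher (adjusted p = 6.4e-08), although 69.8% of the Apoa4 exons overlap a gene on the opposite strand, Gm47528. Region markers were measured as well, of which Lct and Mep1a are also on the enterocyte list. Of 8 proximal small intestinal markers, 6 rose and 2 fell (Pdx1 and Cybrd1), also when adjusted over the list alone (adjusted p = 0.00583, and adjusted p = 0.327 with an estimated correlation). Adh1 was 3-fold and Cyp2b10 6.23-fold higher. Of 8 distal markers 3 rose and 0 fell, on either adjustment (adjusted p = 0.0164, and adjusted p = 0.163 with an estimated correlation), namely the bile acid transporter subunit Slc51a (3.75-fold), Osr2 (1.89-fold) and Fgf15. Among 8 colon markers 3 rose (Slc26a3 3.24-fold, Aqp8 11.2-fold and Cdx1) and 2 fell (Muc4 and Slc37a2), with 4 and 2 adjusted over the list alone (adjusted p = 0.371).

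Crypt base stem cell markers fell in 15 of 17 cases and rose in 1 (Prom1, log2 fold change 0.35), also when adjusted over the list alone (adjusted p = 2.26e-07, and adjusted p = 0.102 with an estimated correlation). Olfm4 was 1.9-fold lower (2100 ± 7.2 against 3980 ± 10 CPM) and the water channel Aqp4 was 3.6-fold lower. Wnt targets, several of which are on the stem cell list too, fell in 13 of 17 cases and rose in 0, with 13 and 1 adjusted over the list alone (adjusted p = 2.27e-05, and adjusted p = 0.102 with an estimated correlation). Axin2, a feedback inhibitor of Wnt signalling, was 1.71-fold lower. Proliferation genes fell in 16 of 20 cases and rose in 0, with 18 and 0 adjusted over the list alone (adjusted p = 2.26e-07, and adjusted p = 0.102 with an estimated correlation). Mki67 was 1.43-fold lower, Top2a 1.53-fold lower and the replication helicase subunit Mcm2 1.46-fold lower.

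Markers of Paneth, enteroendocrine and goblet cells fell as well, and those of tuft cells were not called as a list. Of 15 Paneth cell markers, 11 fell and 2 rose (Mptx1 and Mptx2), on either adjustment, including over the list alone (adjusted p = 9.1e-06, and adjusted p = 0.102 with an estimated correlation). Lyz1, the Paneth cell lysozyme, was 3.04-fold lower, and the α-defensins Defa17 and Defa22 were 2.73-fold and 9.66-fold lower, although near-identical defensin copies make single values uncertain. Enteroendocrine markers fell in 14 of 19 cases and rose in 0, with 15 and 0 adjusted over the list alone (adjusted p = 3.87e-08, and adjusted p = 0.113 with an estimated correlation). Glucagon (Gcg) was 6.22-fold lower, somatostatin (Sst) 3.68-fold lower and Chgb, a protein of hormone granules, 2.46-fold lower. Goblet cell markers fell in 10 of 16 cases and rose in 2, with 11 and 2 adjusted over the list alone (adjusted p = 0.0023, and adjusted p = 0.138 with an estimated correlation). Spink4 was 2.64-fold lower and Guca2a 1.71-fold lower, whereas the secreted lectin Zg16 was 2.16-fold higher and Clca1 had a log2 fold change of 0.20. Of 12 tuft cell markers 1 rose (Hpgds, 2.36-fold, adjusted p = 0.049) and 1 fell (Dclk1, 2.01-fold, adjusted p = 0.022), and 0 in either direction adjusted over the list alone (camera adjusted p = 0.177). Hpgds passed in none of the fits without a WT or Smad4 KO library (adjusted p = 0.195, 0.1, 0.169 and 0.082 without WT replicates 1 and 2 and Smad4 KO replicates 1 and 2), and its adjusted p was 0.0655 with a replicate block and 0.0628 with values divided by 4. Dclk1 did not pass without WT replicate 1 (adjusted p = 0.118) or Smad4 KO replicates 1 and 2 (0.0886 and 0.0667).

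TGF-β/SMAD targets were higher in Smad4 KO organoids even without added TGF-β. Of 15, 7 rose and 0 fell, with 8 and 1 adjusted over the list alone (adjusted p = 0.0086, and adjusted p = 0.138 with an estimated correlation). The cell cycle inhibitor Cdkn2b was 3.88-fold higher (97.9 ± 2.2 against 25.2 ± 0.2 CPM), and the feedback inhibitors of the pathway Pmepa1, Skil and Smad7 were 2.66-fold, 2.75-fold and 2.53-fold higher. Of 8 BMP/SMAD targets, 2 rose (Smad7 and Id1, log2 fold change 0.51) and 1 fell (Id2, 1.33-fold, adjusted p = 0.022), with 2 and 2 adjusted over the list alone (adjusted p = 0.881; the median was 0 and the mean 0.023, and the signs of median, mean and test differed). Id2 did not pass without WT replicate 2 (adjusted p = 0.106) or Smad4 KO replicates 1 and 2 (0.072 and 0.092). Among 20 signalling components of the family, 1 rose (Smad3) and 5 fell (Tgfb1, Bmpr1a, Bmp2, Bmp7, 2.11-fold, and the receptor Tgfbr2, 1.29-fold), the same adjusted over the list alone (adjusted p = 0.626).

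YAP/TAZ targets were mixed, with 7 of 21 higher and 4 lower on either adjustment, including over the list alone (camera adjusted p = 0.177). Myof, a membrane repair protein, was 4.51-fold higher and Wwc1 1.47-fold higher, while F3, the coagulation tissue factor, was 1.73-fold lower; the others lower were Arhgef17, Gadd45b and Fjx1, which was at 0 CPM in both Smad4 KO libraries and at 0.438 CPM in WT. The median was 0.347, or 0.385 with genes at 0 set to their bound. Of 19 Hippo pathway components 2 rose (Wwc1 and Mob1b) and 2 fell (Vgll4, 1.5-fold, and Wwtr1), with 2 and 1 adjusted over the list alone (adjusted p = 0.826, with a median of -0.031 and a mean of 0.043). Fetal and regenerative markers, expressed in fetal gut and in repair after injury, rose in 12 of 19 cases and fell in 1 (Ly6a, log2 fold change -0.45), also when adjusted over the list alone (adjusted p = 1.61e-05, and adjusted p = 0.102 with an estimated correlation). Msln was 8.12-fold higher and the keratin Krt7 1.86-fold higher.

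Extracellular matrix and integrin genes rose in 11 of 20 cases and fell in 2 (Itga6 and Lamb3), on either adjustment, including over the list alone (adjusted p = 0.00885, and adjusted p = 0.138 with an estimated correlation). Thbs1 was 2.48-fold, Itga3 1.97-fold and Itgb5 3.02-fold higher. Epithelial junction and keratin genes rose in 13 of 18 cases and fell in 0, also when adjusted over the list alone (adjusted p = 0.000742, and adjusted p = 0.138 with an estimated correlation). Krt8 was 1.57-fold and the desmosome protein Dsp 1.82-fold higher. Inflammatory mediators rose in 9 of 21 cases and fell in 1 (Ccl28), with 10 and 1 adjusted over the list alone (adjusted p = 0.00187, and adjusted p = 0.138 with an estimated correlation). The antimicrobial lectins Reg3b and Reg3g were 2.99-fold and 2.94-fold higher, and Tnfaip3, an inhibitor of NF-κB signalling, 1.77-fold higher. Of 18 glycolysis and hypoxia genes 12 fell and 2 rose (Ldha and Ndrg1), also when adjusted over the list alone (adjusted p = 0.000681, and adjusted p = 0.138 with an estimated correlation). Ero1l was 2-fold and Pgk1 1.51-fold lower. Cholesterol synthesis genes rose in 8 of 17 cases and fell in 1, with 9 and 1 adjusted over the list alone (adjusted p = 0.00911, and adjusted p = 0.145 with an estimated correlation). Cyp51, an enzyme that removes a methyl group from lanosterol, was 1.35-fold higher.

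Several other lists did not pass as lists. Rises and falls were 7 and 4 of 18 actin and SRF-type genes (8 and 4 adjusted over the list alone, adjusted p = 0.449, with a median of 0.081 and a mean of -0.138), where Myl9, a myosin light chain, was 34.4-fold lower and Acta1, Tpm4 and Actg1 (1.19-fold) also fell. They were 7 and 2 of 13 p53 targets, on either adjustment, including over the list alone (adjusted p = 0.177), with Fas 3.85-fold and Trp53inp1 1.85-fold higher and Sesn2 and Aen lower. EGF family ligands fell in 2 of 6 cases (Areg and Btc) and 3 adjusted over the list alone (adjusted p = 0.138). Of 13 interferon response genes 2 rose, among them Mx1 (8.97-fold), and 1 fell (Ifit2), the same adjusted over the list alone (adjusted p = 0.364). Of 14 unfolded protein and stress response genes 1 rose (Dnajb9, 1.51-fold) and 3 fell (Asns, 1.57-fold, Hsp90b1 and Sesn2), the same adjusted over the list alone (adjusted p = 0.574). Of 6 MHC class II genes 1 fell (H2-Ab1) on either adjustment, including over the list alone (adjusted p = 0.364), and of 5 mesenchymal transition genes 1 rose (Fn1) and 1 fell (Vim), with 3 and 2 adjusted over the list alone (adjusted p = 0.747). The rise of Fn1 rests on few fragments, with 36 units in Smad4 KO and 4 in WT.

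Markers of other cell types and of quality were measured beside these groups. Immediate early and dissociation genes rose in 4 of 12 cases (Hspa1b, 4.64-fold, Hspa1a, 4.23-fold, Fosb and Zfp36) and fell in 2 (Egr1 and Ier3), with 5 and 3 adjusted over the list alone (adjusted p = 0.475). Of 6 leukocyte markers 1 rose (Cd52, at 0 CPM in WT and 0.326 CPM in Smad4 KO), and 0 adjusted over the list alone (adjusted p = 0.449). In the lists of 2 fibroblast, 2 endothelial and 5 sex-linked genes, 0 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.365, 0.879 and 0.826). Mitochondrial transcripts took 4.57% to 4.7% of the units in WT and Smad4 KO libraries. Of 10 mitochondrially encoded genes 4 rose (mt-Atp6, 5.64-fold, mt-Nd4, mt-Nd5 and mt-Cytb) and 2 fell (mt-Co1, 1.07-fold, and mt-Co2), with 5 and 2 adjusted over the list alone (adjusted p = 0.248). The exons of mt-Atp6 overlap mt-Atp8 over 6.5% of their length. The mean of mt-Atp8, given at the end, was not lower in Smad4 KO than in WT, so it shows no matching loss of reads. How reads were assigned is not known, and the value of mt-Atp6 is uncertain here and in the other comparisons.

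Among single genes the largest rises by the fixed rule were in Ugt1a6b (115-fold, adjusted p = 4.6e-06), a glucuronosyltransferase for which 60.6% of the exons overlap Ugt1a7c, Lor (28.5-fold), Ranbp3l (28.3-fold), Tmigd1 (24.6-fold) and the magnesium channel Trpm6 (24.2-fold). The folds of Lor, Ranbp3l, Tmigd1 and Trpm6 rest on 29, 18, 36 and 54 units in WT. Tmigd1 had a log2 fold change of 4.62, and of 5.34 without WT replicate 2. The largest falls were in Emid1, at 0 CPM in Smad4 KO and 6.42 CPM in WT (at least 42.8-fold lower), Exosc6, Myl9, Defa29 (17.2-fold) and Armh4 (14.8-fold). Exosc6 stood at 45.83 and 0.27 CPM in the WT libraries and its exons lie fully within Aars, and its log2 fold change of -7.64 (adjusted p = 0.049) was -1.25 (adjusted p = 0.456) without WT replicate 1. Exosc6 moved to -8.63 without WT replicate 2 (adjusted p = 0.00024) and to -8.23 without Smad4 KO replicate 1 (0.178), and it did not pass without Smad4 KO replicate 2 (0.192), without TGF-β-treated replicate 1 (0.0781) or 2 (0.0768), with a replicate block (log2 fold change -6.83, adjusted p = 0.0602), in the 4 libraries alone (0.0774) or with values divided by 4 (0.0541). Armh4 did not pass without WT replicate 1 (adjusted p = 0.0505) or Smad4 KO replicate 1 (0.0534).

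**Figure D1:**
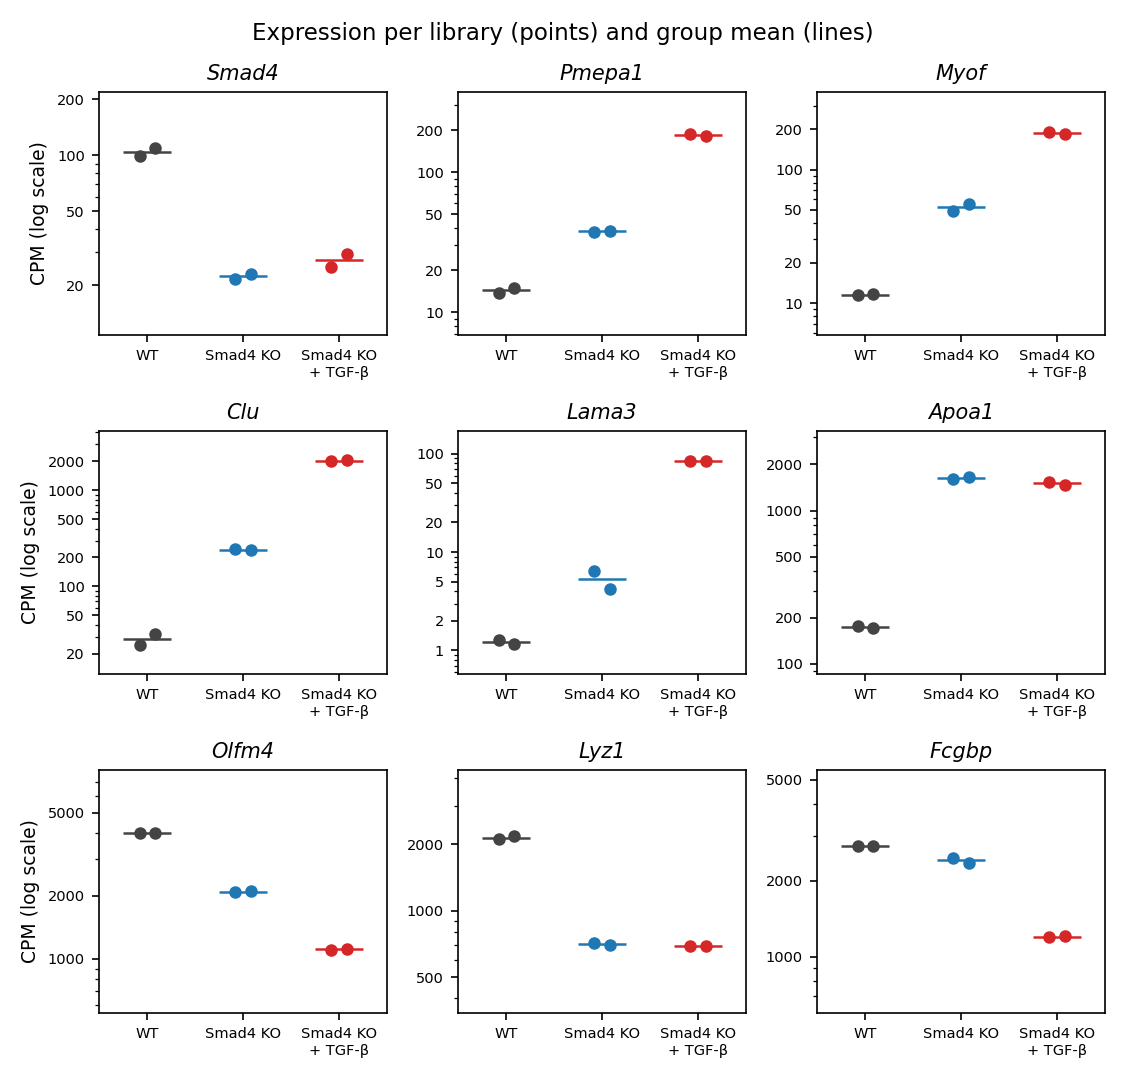
Expression of 9 genes in CPM on a log scale, with each point a library and each line the mean of the 2 libraries of WT, Smad4 KO and TGF-β-treated Smad4 KO organoids. Smad4 fell from 104 to 22.4 CPM in Smad4 KO, Clu rose from 28.4 to 241 and then 2030 CPM, and Lyz1 fell from 2150 to 706 CPM in Smad4 KO.

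The second comparison, Smad4 KO with TGF-β against Smad4 KO, sets organoids labelled Smad4 KO with added TGF-β against those without it. If 48 h were followed by 2 more days, as the protocol can be read, time in culture may differ as well. Its effect could not then be told apart from that of TGF-β. YAP/TAZ targets, TGF-β/SMAD targets, fetal and regenerative markers, and extracellular matrix and integrin genes rose, and enterocyte and goblet cell markers fell. With an estimated correlation the TGF-β/SMAD targets did not pass (adjusted p = 0.0773), and the other lists named here did (adjusted p = 0.0427 to 0.0451). Clu was 8.44-fold higher (2030 ± 44 against 241 ± 4.5 CPM, n = 2 per group), Myof 3.59-fold higher (188 ± 4.4 against 52.3 ± 4.1 CPM) and Pmepa1 4.86-fold higher (184 ± 3.7 against 37.9 ± 0.4 CPM). The sucrase Sis of the enterocyte brush border was 2.34-fold lower (1180 ± 2.8 against 2770 ± 11 CPM). In edgeR 2521 genes passed, 1206 higher and 1315 lower, and 396 and 244 of these differed more than 2-fold. The number higher was 768 without Smad4 KO replicate 2 and 656 and 658 without TGF-β-treated replicates 1 and 2, and the number lower was 869 and 862 without Smad4 KO replicates 1 and 2 and 848 and 876 without TGF-β-treated replicates 1 and 2.

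Of 21 YAP/TAZ targets 12 rose and 0 fell, with 15 and 0 adjusted over the list alone (camera adjusted p = 3.41e-09, and adjusted p = 0.0451 with an estimated correlation). The median log2 fold change was 0.908, or 0.851 with genes at 0 set to their bound. Ajuba, a LIM protein that binds Hippo kinases, was 3.54-fold higher and F3 1.88-fold higher. Ccn2 and Ankrd1, members of this list chosen here after their values were seen, rose from 16.5 to 70.9 CPM (adjusted p = 0.00211) and from 0.4 to 3.62 CPM (adjusted p = 0.00995). YAP activity itself was not measured. Hippo pathway components rose in 6 of 19 cases and fell in 0, with 6 and 1 adjusted over the list alone (adjusted p = 0.00805, and adjusted p = 0.133 with an estimated correlation), among them Wwtr1, which encodes TAZ, 1.69-fold and Wwc1 1.37-fold. TGF-β/SMAD targets rose in 9 of 15 cases and fell in 0, with 12 and 1 adjusted over the list alone (adjusted p = 3.84e-06, and adjusted p = 0.0773 with an estimated correlation), including Smad7 (2.56-fold) and Junb (1.83-fold). Cdkn2b of this list stood at 96.36 and 99.53 CPM in Smad4 KO and at 97.68 and 96.02 CPM with TGF-β. Of 8 BMP/SMAD targets 3 rose (Id1, 2.77-fold, Id2 and Smad7) and 0 fell, on either adjustment, including over the list alone (adjusted p = 0.0535). Among 20 signalling components 3 rose (Tgfbr2, 1.47-fold, Smad3 and Acvr1) and 1 fell (Bmp7, 1.83-fold), with 4 and 1 adjusted over the list alone (adjusted p = 0.199).

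Fetal and regenerative markers rose in 15 of 19 cases and fell in 0, with 16 and 0 adjusted over the list alone (adjusted p = 3.97e-13, and adjusted p = 0.0427 with an estimated correlation). Anxa1 was 4.25-fold and Krt7 2.66-fold higher (1250 ± 4.5 against 469 ± 8 CPM). Extracellular matrix and integrin genes rose in 16 of 20 cases and fell in 0, with 17 and 0 adjusted over the list alone (adjusted p = 4.8e-12, and adjusted p = 0.0427 with an estimated correlation). Their median was 1.014, or 0.934 with members at or under the floor in both groups left out. The laminin chains Lama3 and Lama5 were 16-fold and 2.21-fold higher and the collagen receptor Itga2 1.82-fold higher. Epithelial junction and keratin genes rose in 11 of 18 cases and fell in 2 (the claudins Cldn3 and Cldn15), also when adjusted over the list alone (adjusted p = 4.32e-05, and adjusted p = 0.113 with an estimated correlation). Dsp was 1.77-fold and Krt8 1.47-fold higher. Actin and SRF-type genes rose in 8 of 18 cases and fell in 3 (Acta1, Actg1 and Myl9), with 10 and 3 adjusted over the list alone (adjusted p = 0.0106, and adjusted p = 0.133 with an estimated correlation). The actin cross-linker Flna was 1.68-fold and Actb 1.3-fold higher. Of 5 mesenchymal transition genes, 1 rose (Fn1) and 0 fell on either adjustment, including over the list alone (adjusted p = 0.982), and the log2 fold change of Vim was -0.45 (adjusted p = 0.334).

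Enterocyte markers fell in 21 of 25 cases and rose in 1 (Vil1, log2 fold change 0.17), with 22 and 1 adjusted over the list alone (adjusted p = 3.48e-13, and adjusted p = 0.0427 with an estimated correlation). The glucose transporter Slc5a1 was 2.06-fold lower (454 ± 8.3 against 933 ± 5 CPM). Goblet cell markers fell in 13 of 16 cases and rose in 0, with 14 and 0 adjusted over the list alone (adjusted p = 2.14e-11, and adjusted p = 0.0427 with an estimated correlation). Fcgbp, a protein of mucus, was 2-fold, Zg16 3.28-fold and Spink4 1.71-fold lower. Crypt base stem cell markers fell in 10 of 17 cases and rose in 1 (Prom1), also when adjusted over the list alone (adjusted p = 0.00194, and adjusted p = 0.116 with an estimated correlation). Olfm4 was 1.89-fold, Aqp4 4.4-fold and Lgr5 1.87-fold lower. Of 17 Wnt targets 3 rose (Ccnd1, 1.83-fold, Nkd1 and Ephb2) and 3 fell (Lgr5, Axin2 and Sox9), with 5 and 3 adjusted over the list alone (adjusted p = 0.0939), with a median of 0.305, or 0.211 with genes at 0 set to their bound; 23.4% of the Ccnd1 exons overlap a gene on the opposite strand.

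Paneth cell markers rose in 3 of 15 cases (Mmp7, 1.85-fold, Ang4 and Habp2) and fell in 3 (Mptx1, 6.3-fold, Mptx2, 5.93-fold, and Defa22), with 4 and 3 adjusted over the list alone (adjusted p = 0.433). None of 19 enteroendocrine markers passed in edgeR, with 0 and 0 adjusted over the list alone (adjusted p = 0.944). Chgb stood at 208 ± 8.2 against 220 ± 6.3 CPM (adjusted p = 0.26). None of 20 proliferation genes passed either, with 0 and 0 adjusted over the list alone (adjusted p = 0.578). Mki67 stood at 388 ± 2 against 417 ± 9.2 CPM (adjusted p = 0.074). Of 12 tuft cell markers 1 rose (Il17rb, 1.85-fold, adjusted p = 0.042), and 0 adjusted over the list alone (adjusted p = 0.819, with the signs of median, mean and test differing). Il17rb passed in no fit that left out a library (adjusted p = 0.0679 and 0.0635 without WT replicates 1 and 2, 0.102 and 0.15 without Smad4 KO replicates 1 and 2, and 0.186 and 0.0737 without TGF-β-treated replicates 1 and 2), nor with a replicate block (0.0537) or in the 4 libraries alone (0.0628).

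Region markers fell as lists, although Lct and Mep1a stand on the enterocyte list too. Proximal markers fell in 5 of 8 cases (Adh1, 2.02-fold, Lct, 1.95-fold, Gata4, Cyp2b10 and Slc40a1) and rose in 2 (Onecut2 and Cybrd1), with 6 and 2 adjusted over the list alone (adjusted p = 0.0162, and adjusted p = 0.302 with an estimated correlation). Distal markers fell in 3 of 8 cases (Mep1a, 2.03-fold, Slc51a, 1.39-fold, and Fabp6), with 4 adjusted over the list alone (adjusted p = 0.0121, and adjusted p = 0.133 with an estimated correlation), and colon markers fell in 3 of 8 cases (Aqp8, 3.31-fold, Slc26a3, 1.52-fold, and Cdx1), also when adjusted over the list alone (adjusted p = 0.0121, and adjusted p = 0.133 with an estimated correlation). Slc51a (adjusted p = 0.032) did not pass without Smad4 KO replicates 1 and 2 (0.136 and 0.103), without TGF-β-treated replicates 1 and 2 (0.0603 and 0.151) or with a replicate block (0.0616).

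Inflammatory mediators rose in 7 of 21 cases and fell in 2 (Ccl28 and Reg3g), with 12 and 3 adjusted over the list alone (adjusted p = 0.00194, and adjusted p = 0.116 with an estimated correlation). The chemokine Cxcl16 was 2.05-fold, Tnfaip3 2.03-fold and Nfkbia 1.61-fold higher. EGF family ligands rose in 4 of 6 cases (Ereg, 2.1-fold, Areg, 1.66-fold, Tgfa and Btc), with 5 adjusted over the list alone (adjusted p = 0.00157, and adjusted p = 0.133 with an estimated correlation). Of 13 p53 targets 4 rose (Zmat3, 1.38-fold, Pmaip1, 1.36-fold, Phlda3 and Ccng1) and 0 fell, with 8 and 0 adjusted over the list alone (adjusted p = 0.00194, and adjusted p = 0.133 with an estimated correlation). Ereg did not pass without Smad4 KO replicate 2 (adjusted p = 0.0667) or TGF-β-treated replicates 1 and 2 (0.0733 and 0.0522), Zmat3 without Smad4 KO replicate 2 (0.0557) or TGF-β-treated replicate 2 (0.0556), and Pmaip1 without Smad4 KO replicate 2 (0.0756) or TGF-β-treated replicate 1 (0.0729). Glycolysis and hypoxia genes fell in 13 of 18 cases and rose in 0, with 15 and 0 adjusted over the list alone (adjusted p = 6.6e-07, and adjusted p = 0.0913 with an estimated correlation). Ndrg1 was 1.8-fold and Pgk1 1.44-fold lower. Cholesterol synthesis genes fell in 10 of 17 cases and rose in 1, with 12 and 1 adjusted over the list alone (adjusted p = 0.000453, and adjusted p = 0.113 with an estimated correlation). The sterol sensor Insig1 was 1.55-fold lower. Unfolded protein and stress response genes fell in 5 of 14 cases (Xbp1, 1.35-fold, Asns, 1.28-fold, Trib3, Hspa5 and Hsp90b1), with 6 adjusted over the list alone (adjusted p = 0.0121, and adjusted p = 0.133 with an estimated correlation).

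Immediate early and dissociation genes, which respond to handling as well as to signals, rose in 5 of 12 cases (Hspa1b, 2.5-fold, Ier3, 2.89-fold, Fos, Junb and Hspa1a) and fell in 0, on either adjustment, including over the list alone (adjusted p = 0.000201, and adjusted p = 0.133 with an estimated correlation). All 10 mitochondrially encoded genes fell, also when adjusted over the list alone (adjusted p = 5.01e-05, and adjusted p = 0.3 with an estimated correlation). Among them, mt-Co1 was 1.25-fold and mt-Nd1 1.28-fold lower, and the mitochondrial share of units was 3.92% and 3.87% with TGF-β against 4.57% and 4.64% in Smad4 KO. Of 13 interferon response genes 1 rose (Ifit2), also over the list alone (adjusted p = 0.189). In the lists of 6 MHC class II and 6 leukocyte genes 0 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.944 and 0.86), and in both the signs of median, mean and test differed. Over all genes, 0 also passed among 5 sex-linked genes (adjusted p = 0.578), 2 endothelial genes (adjusted p = 0.378, 1 higher adjusted over the list alone) and 2 fibroblast genes (adjusted p = 0.712, 1 lower adjusted over the list alone). The signs of median, mean and test differed for the fibroblast genes, with a median of 1.837, or -1.034 with genes at 0 set to their bound.

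The largest rises by the fixed rule were in the secreted phosphoprotein Spp1 (96.4-fold, 56 ± 1.3 CPM with TGF-β), fibronectin (Fn1, 86.9-fold), the protease chymosin (Cym, 54.5-fold, 180 ± 3 CPM), Anxa8 (37.5-fold) and Igfbp7 (33.8-fold). The folds of Spp1, Fn1 and Igfbp7 rest on 46, 36 and 28 units in Smad4 KO. The log2 fold change of Igfbp7 was 5.08, and 4.32 and 6.83 without Smad4 KO replicates 1 and 2. The largest falls were in Gvin1 (38.6-fold, adjusted p = 0.025), the sphingomyelinase Enpp7 (6.75-fold, adjusted p = 0.013), Zfp62 (6.67-fold), Mptx1 and the Wnt antagonist Sfrp5 (6.12-fold). Gvin1 and Enpp7 passed in none of the fits without a Smad4 KO library (adjusted p = 0.075 and 0.0622 for Gvin1 and 0.0545 and 0.0519 for Enpp7, without replicates 1 and 2) or a TGF-β-treated library (0.118 and 0.142 for Gvin1, 0.0683 and 0.0774 for Enpp7).

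**Figure D2:**
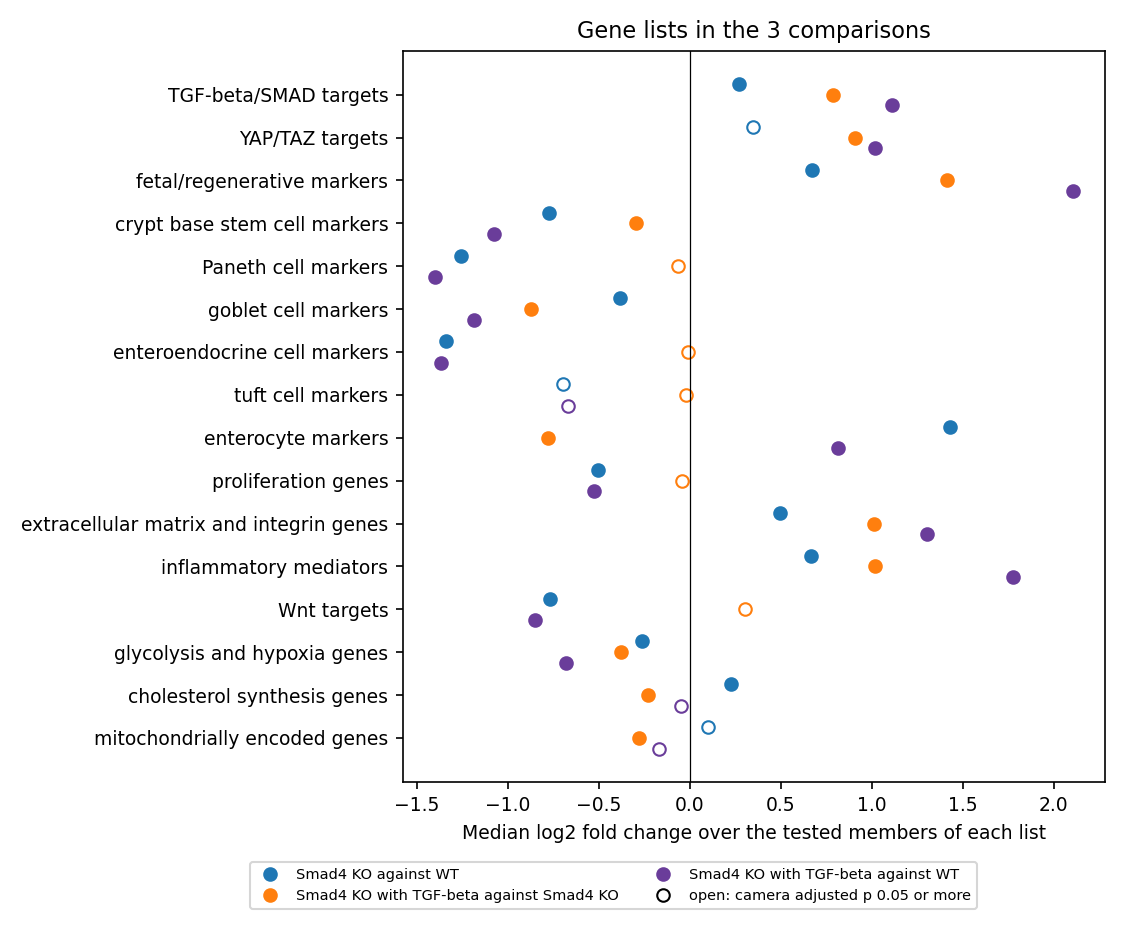
Median log2 fold change over the tested members of each list (x axis) in the 3 comparisons, with open points where the camera adjusted p was 0.05 or more. The median of enterocyte markers was 1.43 in Smad4 KO against WT and -0.78 in Smad4 KO with TGF-β against Smad4 KO, and that of YAP/TAZ targets 0.347 and 0.908.

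The third comparison, Smad4 KO with TGF-β against WT, joins genotype and treatment and is the sum of the other comparisons. Any difference in time in culture, or in organoid line or origin between WT and Smad4 KO, enters it too. Fetal and regenerative markers, YAP/TAZ and TGF-β/SMAD targets and matrix genes rose, and genes of stem cells, of Paneth, goblet and enteroendocrine cells and of the cell cycle fell. No list passed in this comparison with an estimated correlation (adjusted p = 0.0569 or more). Clu was 71.7-fold higher (2030 ± 44 against 28.4 ± 5.3 CPM, n = 2 per group), Myof 16.2-fold and Pmepa1 12.9-fold higher, and Lgr5 3.81-fold lower. In edgeR 6155 genes passed, 3216 higher and 2939 lower, with 1125 and 890 of these changed more than 2-fold.

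Fetal and regenerative markers rose in 15 of 19 cases, YAP/TAZ targets in 13 of 21, TGF-β/SMAD targets in 13 of 15 and matrix and integrin genes in 17 of 20, with 0 falling in each. Adjusted over the list alone, the rises were 15, 15, 14 and 17 (camera adjusted p = 5.76e-09, 1.07e-05, 1.49e-06 and 3.34e-08, and adjusted p = 0.0569 with an estimated correlation for each). Anxa1 was 10-fold, Krt7 4.95-fold, Ajuba 4.75-fold, Wwc1 2.02-fold, Cdkn2b 3.84-fold and Skil 3.59-fold higher. Of these, Cdkn2b differed little between Smad4 KO with and without TGF-β (96.9 against 97.9 CPM). Hippo pathway components rose in 7 of 19 cases and fell in 1 (Vgll4), on either adjustment, including over the list alone (adjusted p = 0.0254, and adjusted p = 0.162 with an estimated correlation). The TEAD-family factor Tead4, through which YAP acts, was 7.1-fold higher. Of 8 BMP/SMAD targets 3 rose (Smad7, 6.48-fold, Id1, 3.95-fold, and Id2) and 0 fell, with 3 and 1 adjusted over the list alone (adjusted p = 0.328). Signalling components rose in 5 of 20 cases (Smad3, 1.79-fold, Tgfb3, Tgfbr2, Acvr1 and Acvr1b) and fell in 3 (Bmp7, 3.85-fold, Bmpr1a and Bmp2), also when adjusted over the list alone (adjusted p = 0.529). Inflammatory mediators rose in 13 of 21 cases and fell in 1 (Ccl28), with 14 and 1 adjusted over the list alone (adjusted p = 6.29e-06, and adjusted p = 0.0569 with an estimated correlation).

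Crypt base stem cell markers fell in 14 of 17 cases and rose in 1 (Prom1), and goblet cell markers fell in 15 of 16 and rose in 0. Adjusted over the list alone, 15 and 15 fell (adjusted p = 2.24e-07 and 5.76e-09, and adjusted p = 0.0569 with an estimated correlation for both). Paneth cell markers fell in 12 of 15 cases and rose in 2 (Mmp7 and Habp2), and enteroendocrine markers fell in 16 of 19 and rose in 1 (the hormone gene Pyy), also when adjusted over the list alone (adjusted p = 1.07e-05 and 5.15e-07, and adjusted p = 0.068 and 0.0815 with an estimated correlation). Proliferation genes fell in 17 of 20 cases and rose in 0, with 18 and 1 adjusted over the list alone (adjusted p = 4.19e-06, and adjusted p = 0.0569 with an estimated correlation). Wnt targets fell in 8 of 17 cases and rose in 3 (Nkd1, Ccnd1 and Cd44), with 9 and 3 adjusted over the list alone (adjusted p = 0.0118, and adjusted p = 0.142 with an estimated correlation). Axin2 was 2.48-fold lower. Enterocyte markers rose in 15 of 25 cases and fell in 5 (Apoc3, Anpep, Slc5a1, Treh and Mep1a), with 16 and 5 adjusted over the list alone (adjusted p = 0.000764, and adjusted p = 0.0795 with an estimated correlation). Of 12 tuft cell markers 2 rose (Ptgs1 and Hpgds) and 2 fell (Dclk1 and Pou2f3), also over the list alone (adjusted p = 0.315).

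All 18 glycolysis and hypoxia genes fell, also when adjusted over the list alone (adjusted p = 3.34e-08, and adjusted p = 0.0569 with an estimated correlation). Ero1l was 2.43-fold and Pgk1 2.17-fold lower. Epithelial junction and keratin genes rose in 14 of 18 cases and fell in 2 (Cldn3 and Cldn15), on either adjustment, including over the list alone (adjusted p = 2.28e-05, and adjusted p = 0.0795 with an estimated correlation). Dsp was 3.22-fold and Krt8 2.32-fold higher. Targets of p53 rose in 10 of 13 cases and fell in 0, with 11 and 2 adjusted over the list alone (adjusted p = 0.00199, and adjusted p = 0.162 with an estimated correlation). Trp53inp1 was 2.3-fold and Ccng1 1.41-fold higher. Proximal markers rose in 6 of 8 cases and fell in 1 (Pdx1), also over the list alone (adjusted p = 0.0254, and adjusted p = 0.366 with an estimated correlation). Cyp2b10 was 4.31-fold and Adh1 1.49-fold higher. Immediate early and dissociation genes rose in 6 of 12 cases and fell in 1 (Egr1), also over the list alone (adjusted p = 0.019, and adjusted p = 0.248 with an estimated correlation). Hspa1b was 11.6-fold and Hspa1a 9.72-fold higher. Of 10 mitochondrially encoded genes 6 fell and 2 rose (mt-Atp6, 4.88-fold, and mt-Cytb), with 7 and 2 adjusted over the list alone (adjusted p = 0.245), and the median was -0.171 against a mean of 0.032. Of 5 mesenchymal transition genes 2 rose (Fn1 and Tagln) and 2 fell (Vim, 3.66-fold, and Snai2), also over the list alone (adjusted p = 0.756). Btc was 1.44-fold lower (adjusted p = 0.017), but did not pass without WT replicate 2 (0.0711) or TGF-β-treated replicates 1 and 2 (0.0544 and 0.0861).

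Actin and SRF-type genes rose in 11 of 18 cases and fell in 3 (Acta1, Actg1 and Myl9), with 11 and 4 adjusted over the list alone (adjusted p = 0.0628). Flna was 2.05-fold and Actb 1.59-fold higher. Of 6 EGF family ligands 2 rose (Tgfa, 1.44-fold, and Hbegf) and 2 fell (Areg and Btc), and of 13 interferon response genes 4 rose, among them Mx1 (7.66-fold), Irf7 and Ifit2. These counts were the same adjusted over the list alone (adjusted p = 0.684 and 0.0824). Cholesterol synthesis genes rose in 3 of 17 cases, among them Sc5d and Mvd, and fell in 5, among them Sqle, Insig1 and Dhcr7. Unfolded protein and stress response genes rose in 1 of 14 (Dnajb9) and fell in 5 (Asns, 2.01-fold, Hsp90b1, 1.23-fold, Xbp1, Trib3 and Chac1), and both counts held adjusted over the list alone (adjusted p = 0.772 and 0.0708). Distal markers rose in 3 of 8 cases (Slc51a, 2.69-fold, Osr2 and Fgf15) and fell in 2 (Mep1a, 1.78-fold, and Cubn). Colon markers rose in 2 of 8 (Slc26a3, 2.14-fold, and Aqp8) and fell in 2 (Muc4, 1.98-fold, and Slc37a2), again on either adjustment, including over the list alone (adjusted p = 0.772 and 0.841). Among markers of other cell types, H2-Ab1 of 6 MHC class II genes and Pdgfrb of 2 fibroblast genes fell, and Csf1r and Cd52 of 6 leukocyte genes and Esam of 2 endothelial genes rose. These counts were also unchanged adjusted over the list alone (adjusted p = 0.422, 0.47, 0.448 and 0.378), and 0 of 5 sex-linked genes passed (adjusted p = 0.496).

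The largest rises by the fixed rule were in genes at or near 0 in WT. Spp1 was at least 449-fold, Mcpt2 at least 71-fold, Gulp1 at least 63.5-fold and Xlr4a at least 49-fold higher, and the ratio for Cym was 2160 (95% counting interval 599 to 17900). Fibronectin (Fn1) had a ratio of 949 (counting interval 170 to 37500), and was at 0 CPM in 1 WT library. Its fitted log2 fold change, which has no upper limit where WT is at 0, was 9.79, and 8.71 and 13.76 without WT replicates 1 and 2. Among the largest falls, Adgrd1 and Emid1 were at 0 CPM with TGF-β (at least 56.8-fold and 46.8-fold lower), and Myl9 and Defa29 were 103-fold and 31.7-fold lower. The fold of Myl9 rests on 25 units in the treated group. The urea transporter Slc14a1 had a log2 fold change of -6.86, and of -7.82 without TGF-β-treated replicate 2.

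Many genes changed in both steps, from WT to Smad4 KO and from Smad4 KO to Smad4 KO with TGF-β. Clu, Myof, Pmepa1 and Krt7 were among 516 genes that rose in both, and Lgr5, Olfm4 and Aqp4 among 350 that fell in both. Sis and Adh1 were among 518 that rose and then fell, and F3 and Tgfbr2 among 176 that fell and then rose. Independent lists of the same lengths would share 204, 177, 222 and 162 genes. The numbers were 0, 0, 0.05 and 0.15 on average in 20 simulations in which nothing changed but the Smad4 KO libraries were shared. Those simulations leave out the effects and so have few calls to share, and the independent lists leave out the shared libraries, so an excess over either is not a measure of shared effects. The log2 fold changes of the steps correlated at 0.0492 across 12717 genes, which are not independent replicates, against -0.505 in the simulations, and their covariance was 0.025 against -0.0445, a difference of 0.0695. Sharing the Smad4 KO libraries pushes the steps in opposite directions, and the group was not split between the steps, since each step would keep 1 Smad4 KO library. Part of the 518 and 176 genes that turned may therefore come from it, while it lowers the numbers that moved the same way. Leaving out Smad4 KO replicate 1 or 2 gave 325 and 292 genes higher in both and 198 and 202 lower in both, and TGF-β-treated replicate 1 or 2 gave 315 and 313 higher in both. Genes lower in both numbered 231 without WT replicate 1 and 219 without TGF-β-treated replicate 1, and those that fell and then rose 88 and 92 without WT replicates 1 and 2, 113 without Smad4 KO replicate 2, and 78 and 72 without TGF-β-treated replicates 1 and 2.

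**Figure D3:**
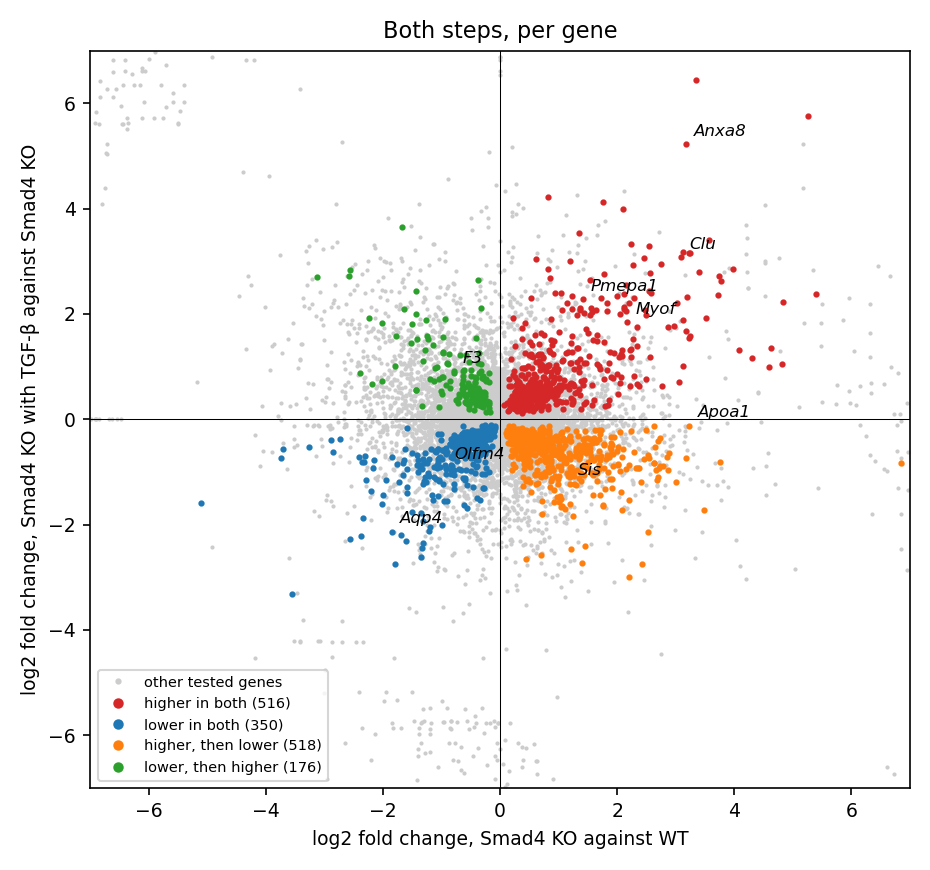
Log2 fold change of each gene in Smad4 KO against WT (x axis) and in Smad4 KO with TGF-β against Smad4 KO (y axis), with genes that passed in both coloured by direction. The axes end at 7 in each direction and show 15336 genes, with 167 outside, and 516 genes rose in both steps while 518 rose and then fell.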

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

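Division of the values by 4 was chosen after the data were seen; all other alternatives were planned. No gene called in any of the 3 comparisons was called in the opposite direction under any alternative run. With RLE size factors, DESeq2, no filter, the 4 libraries alone or division by 4, the counts of changed genes stayed within 1.5 times those reported. RLE kept 99.2%, 98.5% and 98.1% of the calls of the 3 comparisons, and DESeq2 99.8%, 99.8% and 99%. A test against a fold change of 1.5, which asks for a larger effect by construction, left 700 genes higher and 302 lower in Smad4 KO against WT, 257 and 207 with TGF-β against Smad4 KO, and 1147 and 768 with TGF-β against WT, and the share of higher calls in the first went from 55.7% to 69.9%. Of 197 passing values of named genes, 53 did not pass that test, and 183 passed without each library.

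Leaving out 1 library leaves fewer degrees of freedom and a lone library that is assumed to vary like the other groups. Smad4 KO against WT then had 1166 to 1867 genes lower. Smad4 KO with TGF-β against Smad4 KO had 656 to 1108 higher and 848 to 1196 lower. The numbers higher in both steps ran from 292 to 439, lower in both from 198 to 238, and lower then higher from 72 to 136. As few as 54.6% of the calls remained, with TGF-β against Smad4 KO without TGF-β-treated replicate 1. The called gene lists stayed called without each library.

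With an estimated correlation 0, 5 and 0 of the 35 lists passed in the 3 comparisons, against 16, 21 and 18 with the preset one. The estimated correlation was at or below the preset 0.01 in 21 lists (median -0.0122, range -0.204 to 0.952), so the loss follows at least in part from the 3 residual degrees of freedom that this form uses. With fry, which tests whether a list moves on balance and not against other genes, 25, 26 and 28 lists passed.

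Replicate numbers did not pair the samples, because the labels tie them to no shared culture or day and deviations of same-numbered libraries correlated at 0.00135, 0.0118 and 0.0138. With the replicate block, 2385 genes were higher and 1799 lower in Smad4 KO against WT, 1018 and 1135 with TGF-β against Smad4 KO, and 2999 and 2668 with TGF-β against WT, and all 16, 21 and 18 lists stayed called. Genes named at 0 in all libraries of a group had fitted fold changes that moved with division by 4 and are given as bounds.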

Other observations

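The tests of the stem families, of region and of remaining wild-type cells were chosen after results were seen, and those of GC content, exon length and linked genes before. Gene families were read from shared symbol stems, 227 stems in all, and none of those named here passed camera with an estimated correlation (adjusted p = 0.749 or more). In Smad4 KO against WT, 19 of 20 Defa genes fell (median log2 fold change -2.76, camera adjusted p = 3.47e-15), though near-identical copies make single members uncertain. Rises were seen in 11 of 15 Ugt genes (glucuronosyltransferases, median 1.74, adjusted p = 1e-05) and 10 of 14 Ces genes (carboxylesterases, 1 fell, adjusted p = 0.00223). Of 48 Cyp genes 22 were higher and 3 lower (adjusted p = 0.00286). Members of the Ugt stem can share exons, as Ugt1a6b does with Ugt1a7c, so they are not all separate measurements. Annexins rose in 9 of 12 cases (adjusted p = 0.00477), and Rpl genes of the large ribosomal subunit fell in 25 of 50 (median -0.186, adjusted p = 0.00296).

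With TGF-β against Smad4 KO, falls were seen in 9 of 15 Ugt genes (median -0.758, adjusted p = 0.000345) and 8 of 14 Ces genes (adjusted p = 0.00161). Of 48 Cyp genes 21 fell and 3 were higher (adjusted p = 0.00286). Both comparisons share the Smad4 KO libraries, which pushes them in opposite directions, and this was not measured for these stems. Annexins rose in 8 of 12 cases and fell in 1 (median 0.964, adjusted p = 0.000202), and keratins rose in 9 of 22 and fell in 1 (adjusted p = 0.00388). Rpl genes fell in 18 of 50 cases (adjusted p = 0.000435) and Rps genes of the small subunit in 19 of 44, with 1 higher (adjusted p = 0.0249). For each of these families the adjusted p was 0.787 with an estimated correlation.

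Enterocyte genes rose in Smad4 KO organoids (camera adjusted p = 8.6e-15, and adjusted p = 0.097 with an estimated correlation). GC content and exon length argue little for this, because the list kept 104% of its median after their trend was removed (1.43 before and 1.48 after, 95% interval 0.842 to 1.739). Organoids from different stretches of the small intestine stay open: medians of proximal minus distal markers off the enterocyte list, 7 of each, differed by -0.129 (interval -2.271 to 0.934, exact permutation p = 0.534 over 3432 permutations, 2-sided), which is too wide to decide. A hypothesis that loss of Smad4 shifts these cultures toward absorptive cells may hold, but origin cannot be told apart from genotype here, and several WT and Smad4 KO lines from the same stretch of intestine would test it.

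TGF-β/SMAD and YAP/TAZ targets rose with TGF-β in organoids that carry the Smad4 KO label (camera adjusted p = 0.0773 and 0.0451 with an estimated correlation). Immediate early and dissociation genes rose too (0.133), Junb being on both this list and the TGF-β/SMAD list, while all 10 mitochondrially encoded genes fell (0.3). Neither handling nor a difference in time in culture was tested as a cause. Removing the trend over GC content and exon length kept 83.4% of the joint median of the targets (0.834 before and 0.695 after, interval 0.48 to 1.101). Wild-type cells left in the cultures are another possible explanation, since Smad4 stood at 21.5% of its WT level (counting interval 19.4% to 23.8%). Transcript of a deleted allele would be counted too, so this share need not come from wild-type cells. If it did and those cells kept their WT expression, almost no gene would lie below this share. Of 10657 genes at 5 CPM or more in WT, 28 had an upper counting limit in Smad4 KO below 19.4% of WT. For 4 the limit was below 0.25 of that value. Of the 28, 9 are defensins and Fam177a, Acat3 and Gm28901 did not pass in edgeR (adjusted p = 0.0898, 0.112 and 0.162), and of the 4, Fam177a did not pass and Exosc6 rests on 1 WT library, which leaves Emid1 and Myl9. The criterion was rewritten after these counts were seen, and under the one written first the 4 would have favoured remaining wild-type cells. The explanation therefore stays open, and a response that does not need Smad4 is a hypothesis. A WT group with TGF-β, not analysed here, would show whether the response differs by genotype. It would not tell such a response from one of remaining wild-type cells, for which cultures free of them would be needed.

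Genes changed between Smad4 KO and WT could in part lie near the targeted allele, where another strain's variants travel with it. Within 10 Mb of Smad4, 26 of 84 genes passed (31%), against 4675 of 15409 elsewhere (30.3%), with an odds ratio of 1.03 (95% interval 0.621 to 1.66, Fisher's exact p = 0.906). Odds of 2 or more lie outside that interval. Smad7 (chromosome 18, from 75367529) and Slc14a1 (from 78100091) lie in this window and passed. A share over the whole window does not show whether single genes in it carry such an effect. Strain or line differences spread over the genome would enter both shares, so this comparison cannot show them.

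The mitochondrial gene mt-Atp6 stood at 454.96 and 486.56 CPM in WT, 2651.07 and 2654.72 CPM in Smad4 KO and 2293.02 and 2303.69 CPM with TGF-β, while its overlapping neighbour mt-Atp8 stood at 466.3, 546.8 and 485.3 CPM on average. Gvin1 stood at 30.65 and 2.78 CPM in the WT libraries, 37.95 and 27.95 CPM in Smad4 KO and 1.06 and 0.64 CPM with TGF-β.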
